A study of Mus musculus with 10 samples.

How the data were processed

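Total RNA of the prostates of 10 male TRAMP mice, 5 given tap water and 5 given nicotine in tap water, was extracted with Trizol, amplified, labelled with biotin and hybridised to single-colour Affymetrix whole-transcript arrays, per the labels. Separate numbers in the labels mark separate mice, with 1 array each. The authors deposited 1 table of log2 values, with 35556 probe sets and 10 arrays. Background correction, summarisation and normalization are not given in the sources used here; the values ran from 3.59 to 14.1, the array medians from 7.50 to 7.57, and genes were not centred. The scale was read as log2 from this range. No scanner files, scan dates or slide numbers were used here, so batches could not be checked.

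Probe sets were named from the platform annotation, which can be old: 21789 of 35556 had 1 gene symbol, 1621 had several and 12146 were unnamed in that table. Of the first kind, 21698 matched a RefSeq gene of assembly GRCm38.p6 by Entrez identifier, and 0 symbols changed. Genes were taken from probe sets with 1 symbol only, giving 19938 genes, of which 999 had several probe sets, and the probe set with the highest mean over all arrays was kept. The 25% of genes with the lowest mean, below 6.55 log2 units, were left out, and 14953 genes were tested. Reference coordinates were not used, because the build of the annotation is not given in the sources used here.

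Nicotine was compared with water with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on the log2 values of all 10 arrays, two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. SEs of genes are those of the moderated fit; SEs of list means are between mice, from an ordinary two-group fit or, with the seminal vesicle covariate, an ordinary linear fit. Before the data were examined, 32 gene lists were fixed, 10 of them immune or inflammation lists and several of them markers of other cell types, with 700 members of which 553 were tested. The 31 lists with at least 5 tested members were tested with limma camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Beside it, camera with a correlation estimated from the data, fry and an exact two-sided permutation test of the list mean per mouse were run. With 5 against 5 mice the permutation test has 252 arrangements and cannot give a p below 0.00794; with 3 against 5 it has 56 arrangements and cannot give one below 0.0179. The immune lists were also pooled, each gene once, into 235 genes of which 164 were tested, and the mean per mouse was compared by the same permutation test. Lists share members, so their tests are not independent. Genes or list members not named in the text are summarised by count, and some genes of the lists and of the rule below are not analysed here.

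The genes named in the text followed a rule fixed before the data were examined. It took 12 genes in each direction by size among those past the threshold or, as 0 passed, those with the smallest unadjusted p, leaving out predicted and clone names. From each list it took up to 4 members with the smallest unadjusted p, and it added Pbsn and the nicotinic receptor subunits as a range with up to 4 examples. In practice 3 members were taken from lists called by camera and 2 from the other tested lists. The number of members named therefore followed the test result. Genes named outside this rule are said to be chosen after their values were seen.

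The mouse numbers 1 to 5 occur in both groups, and the labels do not say that a number is shared. Alternatives fixed before the data were examined were another filter on low genes, other rules for several probe sets, quantile normalization again, centring on array medians, a trended and robust eBayes, array weights, the mouse number as a block, the first principal component as a covariate, leaving out each mouse in turn and, for the pooled immune genes, scaling each gene. Leaving out nicotine mice 1 and 3 and using the seminal vesicle list mean as a covariate were added after the data were seen, as was the grouping of the mice by seminal vesicle content at 10 log2 units. The 2 groups were also compared with other splits of the 10 mice, 100 of the 126 possible.

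The steps were tested on simulated data of 14953 genes, with 200 genes changed in each of 10 simulations of the 10 mice. Genes were drawn independently, each with its real mean and a single spread pooled over both groups. The real spread was wider in nicotine mice, with a median SD of 0.261 against 0.0969 in water mice. Recovery in the real 10 mice can therefore differ from the values below. The test recovered 42.8% of genes changed by 0.5 log2 units, 76.0% at 1, 90.4% at 2 and 99.2% at 4, with 5.49% false among the calls. With the spreads of the 8 mice left without nicotine mice 1 and 3, 80.2% were recovered at 0.5 and 98.4% at 1. In simulated data with independent genes, camera called the proliferation list shifted by 0.5 log2 units in 100% of simulations and other lists in 0.333%; genes of a real list are correlated, which this simulation leaves out.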

Results

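Gene expression was measured on whole-transcript arrays in the prostates of 10 male TRAMP mice, 1 array per mouse. TRAMP mice carry a viral T antigen under the promoter of Pbsn (probasin, a secretory gene of the prostate epithelium) and develop prostate tumours. From an age of 8 to 9 weeks, 5 mice drank tap water and 5 drank tap water with nicotine tartrate giving 250 µg/ml of nicotine. The series belongs to work on an immune and inflammation signature in the prostate tumours of smokers, and this part sets nicotine alone against water. The deposited log2 values had array medians from 7.50 to 7.57, and 14953 genes were tested. The number of arrays, 5 per group, limits the precision.

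The prostates of nicotine mice 3 and 1 stood apart from the other 8 in tissue markers. Neuroendocrine markers, such as the secretory granule gene Chga, averaged 9.84 log2 units in nicotine 3 and 9.43 in nicotine 1, against 7.25 ± 0.25 (SD, n = 5) in water mice. Prostate luminal secretory and androgen-regulated genes averaged 7.46 in nicotine 3 and 10.3 in nicotine 1, against 11.01 ± 0.05 (SD, n = 5) in water mice. Smooth muscle markers averaged 7.94 in nicotine 3 and 9.78 in nicotine 1, against 10.4 ± 0.11 (SD, n = 5). Skeletal muscle markers averaged 9.82 in nicotine 1 and 7.15 in nicotine 3, against 7.33 ± 0.08 (SD, n = 5). Over the tested genes, the median correlation with the other arrays was 0.654 for nicotine 3 and 0.880 for nicotine 1, while the other 8 arrays correlated with each other at 0.980 to 0.993. A second tissue varied within both groups and was spread unevenly over them: seminal vesicle secretory genes averaged 11.95, 13.1 and 12.9 in water mice 3, 4 and 5 and 12.4 in nicotine 5, and between 5.92 and 8.45 in the other 6 mice.

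**Figure D1:**
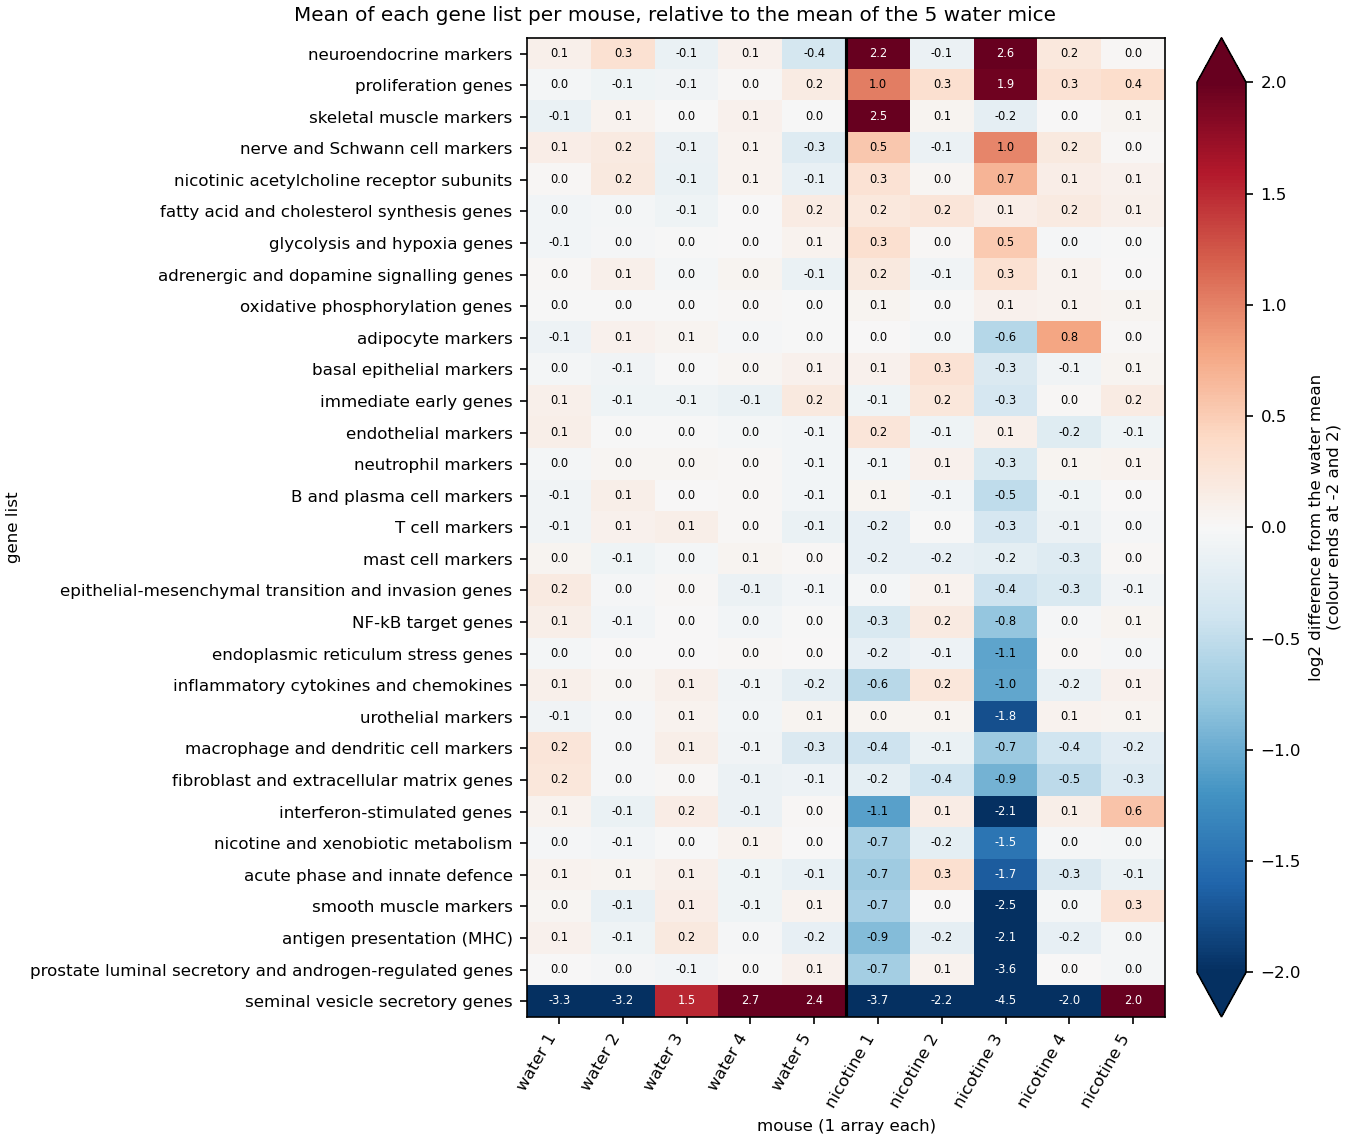
Mean of each gene list (rows) in each mouse (columns) minus the mean of the 5 water mice, in log2 units, with the 5 water mice left of the line and the 5 nicotine mice right of it. Numbers in the cells are the differences, and the colour stops at -2 and 2. Nicotine 3 and nicotine 1 hold most of the dark cells, and the seminal vesicle row splits water mice 1 and 2 from water mice 3, 4 and 5.

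The first question was which genes differ with nicotine. Among the 12 genes with the smallest p in the higher direction, the log2 difference, nicotine minus water, was 0.39 ± 0.07 (SE) for Tk1, the thymidine kinase of S phase, 0.83 ± 0.17 for the cell cycle phosphatase gene Cdkn3 and 0.92 ± 0.22 for the mitotic cyclin gene Ccnb2. It was 0.47 ± 0.11 for Mcm5, part of the replicative helicase, 0.50 ± 0.12 for the centromere gene Cenpm, 0.55 ± 0.13 for the kinetochore gene Pmf1 and 0.87 ± 0.21 for the histone gene H2bc18. The remaining genes of the 12 were Dpy30 (0.28 ± 0.06), Aaas (0.28 ± 0.07), Retreg2 (0.29 ± 0.07) and the small nucleolar RNAs Snord118 (1.06 ± 0.25) and Snora41 (0.56 ± 0.13). All 12 were above every water mouse in all 5 nicotine mice.

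Among the 12 with the smallest p in the lower direction, the log2 difference was -0.95 ± 0.19 (SE) for Cybb, a subunit of the phagocyte NADPH oxidase, and -0.61 ± 0.12 for Cd33, a receptor of myeloid cells. It was -0.83 ± 0.16 for Dpt (dermatopontin, a matrix protein), -0.57 ± 0.12 for Cd34, found on endothelial cells and fibroblasts, and -0.90 ± 0.19 for the transporter gene Abca9. Both autophagy genes in the group, Rb1cc1 and Atg4c, had differences of -0.49 ± 0.11 and -0.36 ± 0.08. The others were Adgrg2 (-0.59 ± 0.10), Arhgap15 (-0.68 ± 0.14), Zdhhc20 (-0.33 ± 0.06), Slc38a9 (-0.28 ± 0.06) and the histone demethylase gene Kdm5a (-0.23 ± 0.05). All but Atg4c were below every water mouse in all 5 nicotine mice.

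None of these 24 genes passed the test: by limma, 0 of 14953 genes were past an adjusted p of 0.05, and the smallest adjusted p was 0.458. At an unadjusted p under 0.05 there were 1514 genes, 640 higher and 874 lower, where chance gives 747.65. With the seminal vesicle list mean as a covariate, added after the data were seen, there were 625, the lowest count of all settings. The groups did not overlap in 733 genes (302 higher and 431 lower), or 4.90% of those tested, where chance gives 0.794%. The spread was wider in the nicotine group, with a median SD per gene of 0.261 against 0.0969 in water mice. Leaving out nicotine mice 1 and 3, an alternative added after the data were seen, 0 genes passed by limma, the smallest adjusted p was 0.0582 and 2198 genes had an unadjusted p under 0.05, of which 989 were among the 1514 with the same direction. With array weights, which lower the influence of aberrant arrays, 425 genes were higher and 671 lower at adjusted p under 0.05. The other 19 planned settings gave 0 genes, so these calls rest on the weights.

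**Figure D2:**
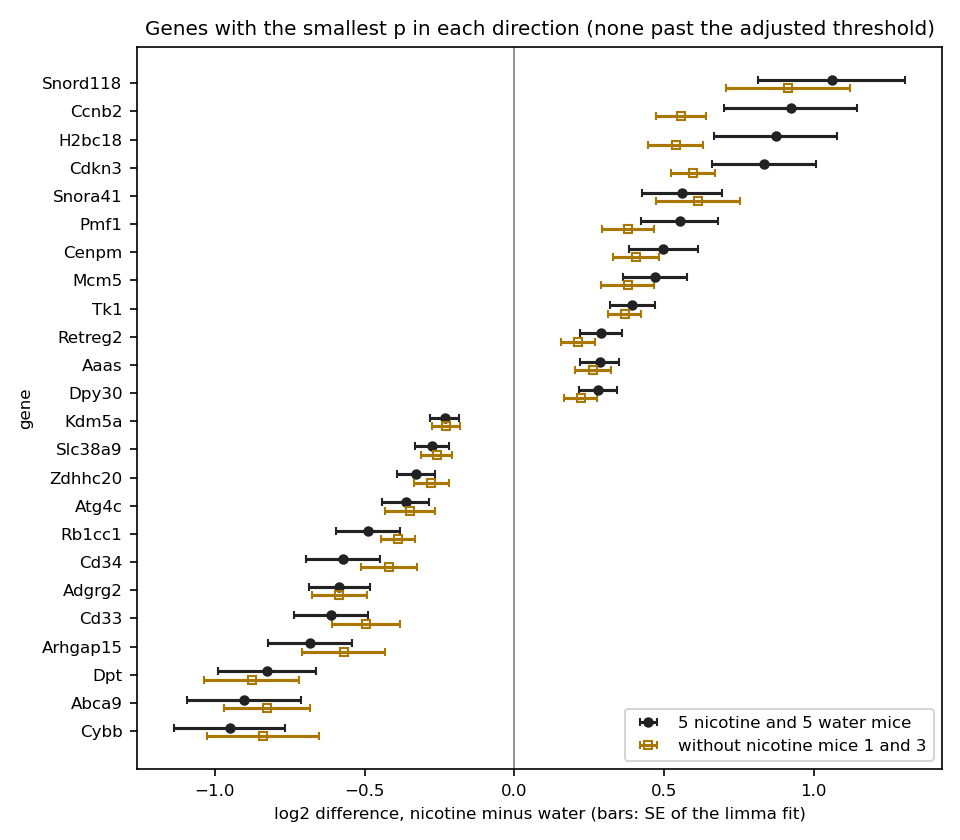
Log2 difference, nicotine minus water (horizontal axis), of the 12 genes with the smallest p in each direction (vertical axis), over all 10 mice (filled points) and without nicotine mice 1 and 3 (open squares). Bars are the SE of the limma fit, and the differences run from -0.95 for Cybb to 1.06 for Snord118 over all 10 mice.

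The second question was which gene lists, fixed before the data were examined, differ with nicotine. Proliferation genes were higher in the nicotine mice: their mean was 9.83 ± 0.71 (SD, n = 5) in nicotine mice and 9.04 ± 0.10 (SD, n = 5) in water mice, a fold of 1.72. All 37 tested members had a positive difference, 19 had groups that did not overlap, and 8 passed when adjusted over the list alone, with 0 past the threshold over all genes. Examples were Mcm5, Ccnb2 and the thymidylate synthase gene Tyms (0.54 ± 0.14 SE). All 5 nicotine mice lay above all 5 water mice. Adjusted p was 7.37e-17 by limma camera with its preset correlation, and adjusted p was 0.614 with an estimated correlation. The estimate between members of the list was 0.80, far above the preset 0.01. The exact permutation p of the list mean was 0.00794, the smallest that 252 arrangements can give, and 0.123 after adjustment over 31 lists. Without nicotine mice 1 and 3 the difference was 0.32, with 30 members past the threshold over the list alone and an exact permutation p of 0.0179, the smallest possible there.

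Fatty acid and cholesterol synthesis genes differed by 0.17 log2 units, from 9.37 ± 0.09 (SD, n = 5) to 9.55 ± 0.06 (SD, n = 5), with 19 of 23 members positive and 0 past the threshold over the list alone. The isoprenoid enzyme gene Fdps (0.31 ± 0.09 SE), the fatty acid synthase gene Fasn (0.33 ± 0.11) and the squalene synthase gene Fdft1 (0.32 ± 0.11) had the smallest p. Adjusted p was 0.000122 by limma camera and adjusted p was 0.614 with an estimated correlation, and the exact permutation p was 0.0238. The difference was also 0.17 without nicotine mice 1 and 3, with an exact permutation p of 0.0536. Oxidative phosphorylation genes differed by 0.05 log2 units, with 20 of 28 members positive, 0 past the threshold over the list alone and Atp5o (0.24 ± 0.06 SE), Ndufb8 (0.26 ± 0.08) and Cox5a (0.23 ± 0.08) as examples. Their adjusted p was 0.0357 by limma camera, adjusted p was 0.614 with an estimated correlation, and the exact permutation p was 0.0159. Without nicotine mice 1 and 3 the difference was 0.04, with a camera adjusted p of 0.173 and an exact permutation p of 0.0357.

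The 3 other lists called higher moved with nicotine mice 1 or 3. Neuroendocrine markers were higher by 0.98 log2 units, with all 18 members positive and none past the threshold over the list alone. Chga (1.74 ± 0.92 SE), Uchl1 (1.27 ± 0.69) and Sez6 (0.55 ± 0.31) were the members with the smallest p. Glycolysis and hypoxia genes were higher by 0.17, with 19 of 26 members positive, although 2 of the 3 members with the smallest p were lower: Hk1 (-0.15 ± 0.06 SE) and Pfkfb4 (-0.25 ± 0.10), against Pkm (0.35 ± 0.15). Skeletal muscle markers were higher by 0.49, with 15 of 16 members positive and values of 1.11 ± 0.87 (SE) for the myosin gene Myl1, 0.64 ± 0.46 for Neb and 0.38 ± 0.30 for Mb. Adjusted p by limma camera was 9.96e-05, 0.0222 and 0.0119 for these 3 lists, and adjusted p was 0.660 for each with an estimated correlation. In the fit without nicotine mice 1 and 3 the differences were 0.04, -0.01 and 0.04, and none of the 3 passed.

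Fibroblast and extracellular matrix genes fell in the nicotine mice. Their mean was 8.89 ± 0.29 (SD, n = 5) against 9.36 ± 0.14 (SD, n = 5) in water mice, and all 5 nicotine mice lay below all 5 water mice. Of 22 members, 21 had a negative difference, 4 had groups that did not overlap and 1 passed over the list alone. Dpt, the proteoglycan gene Lum (-1.42 ± 0.42 SE) and the matrix protein gene Sparc (-0.37 ± 0.12) had the smallest p. Adjusted p was 3.31e-07 by limma camera, adjusted p was 0.614 with an estimated correlation, and the exact permutation p was 0.00794. Without nicotine mice 1 and 3 the difference was -0.40, with 17 members past the threshold over the list alone and an exact permutation p of 0.0179.

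Macrophage and dendritic cell markers fell too, from 8.45 ± 0.20 (SD, n = 5) to 8.07 ± 0.23 (SD, n = 5), with 3 of 5 nicotine mice below all water mice. Of 23 members, 22 had a negative difference, 4 had groups that did not overlap and 7 passed over the list alone. The macrophage surface gene Adgre1 (-0.89 ± 0.21 SE), the growth factor receptor gene Csf1r (-0.79 ± 0.19) and the scavenger receptor gene Cd163 (-0.30 ± 0.07) had the smallest p. Adjusted p was 3.31e-07 by limma camera, adjusted p was 0.614 with an estimated correlation, and the exact permutation p was 0.0238. Without nicotine mice 1 and 3 the difference was -0.25 and the exact permutation p 0.107, with 6 members past the threshold over the list alone.

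**Figure D3:**
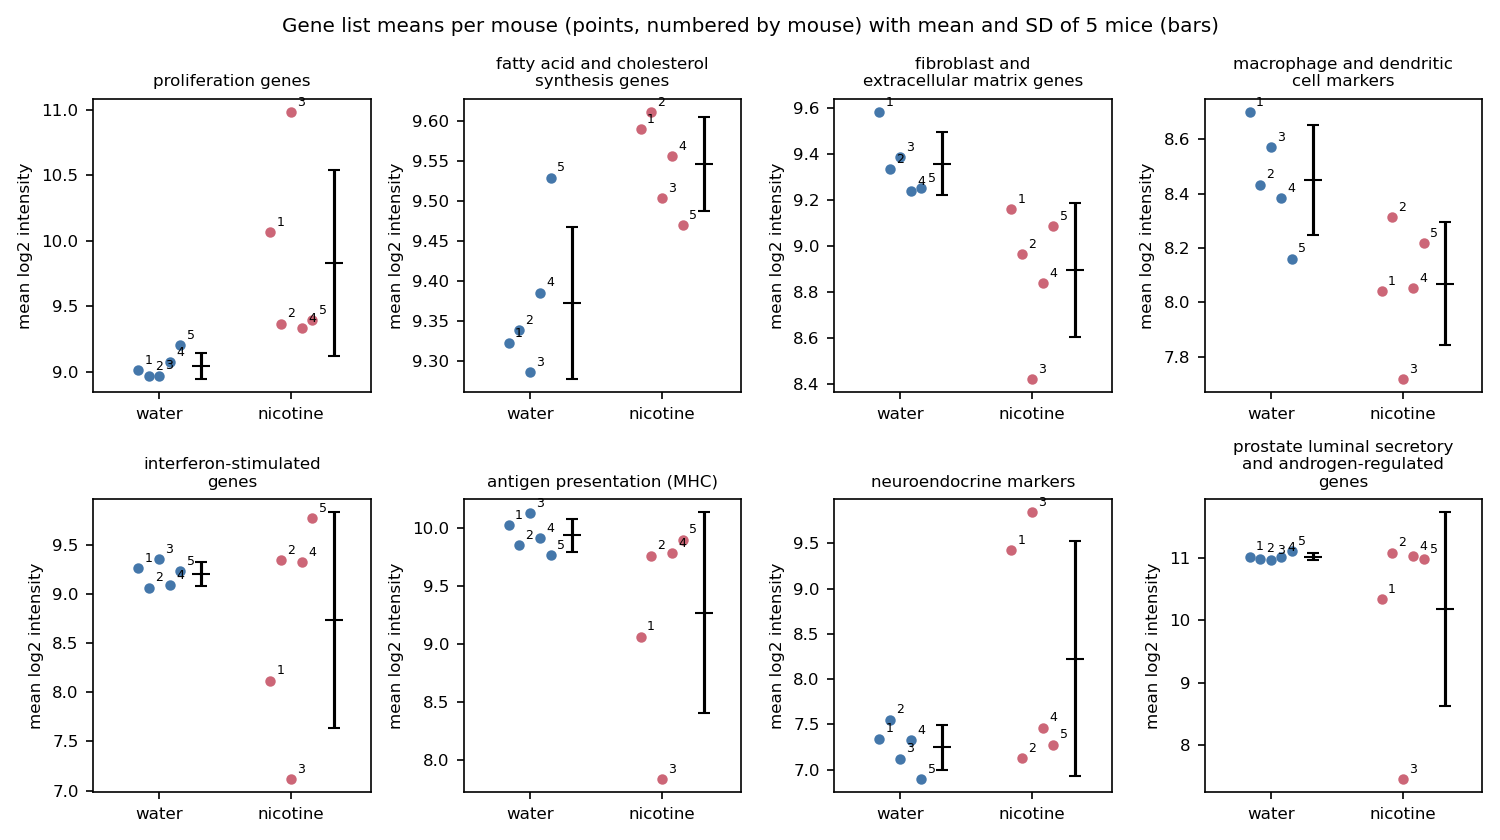
Mean log2 intensity (vertical axis) of 8 gene lists in each mouse, with the mouse number beside each point and the mean and SD of 5 mice as bars. The vertical axes do not start at 0 and differ between panels. In the proliferation list all nicotine mice lie above all water mice, in the fibroblast list all lie below, and in the interferon, MHC, neuroendocrine and luminal lists nicotine 1 and 3 lie far from the other nicotine mice.

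Of the 10 immune and inflammation lists, 5 were called lower, and the means of 4 of these, all but the macrophage list, followed nicotine mice 1 and 3. Antigen presentation genes of the MHC differed by -0.67 log2 units, with 15 of 16 members negative, 1 past the threshold over the list alone, and the smallest p for the protease gene Ctss (-0.71 ± 0.17 SE), H2-Ob (-0.31 ± 0.09) and H2-Eb1 (-0.75 ± 0.31). Acute phase and innate defence genes differed by -0.49, with 10 of 12 members negative, 2 past the threshold over the list alone, and the smallest p for the lysozyme gene Lyz1 (-0.56 ± 0.13 SE), the complement gene Cfb (-0.74 ± 0.19) and Lyz2 (-0.48 ± 0.21). Interferon-stimulated genes differed by -0.47, with 34 of 37 members negative and the smallest p for Cxcl9 (-0.86 ± 0.36 SE), Gbp4 (-0.48 ± 0.25) and Gbp7 (-0.69 ± 0.39). Inflammatory cytokines and chemokines differed by -0.29, with 22 of 27 members negative and the smallest p for Ccl8 (-1.08 ± 0.39 SE), Cxcl1 (0.14 ± 0.07) and Il33 (-1.05 ± 0.52). Adjusted p by limma camera was 4.97e-05, 0.0119, 0.00161 and 0.0483 for these 4 lists, and adjusted p was 0.660 for each with an estimated correlation. With nicotine mice 1 and 3 left out, the differences were -0.12, -0.03, 0.28 and 0.05, and of the 4 lists the interferon-stimulated genes passed by camera, in the higher direction (adjusted p = 5.54e-10), with an adjusted p of 0.655 with an estimated correlation. Over each list alone, 0, 3, 3 and 0 members passed without nicotine mice 1 and 3. Some named members stayed lower there: Ctss by -0.52 ± 0.15 (SE), Lyz1 by -0.42 ± 0.12, Cfb by -0.55 ± 0.17 and Lyz2 by -0.66 ± 0.19. Others, such as Gbp4 (-0.10 ± 0.14) and Gbp7 (-0.06 ± 0.15), did not. Nicotine 5 had the highest interferon-stimulated mean of all 10 mice, 9.77.

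The other 5 immune lists did not pass by limma camera, although with no filter on mean level T cell markers (adjusted p = 0.0143) and B and plasma cell markers (0.0374) passed as lower. Some also passed as lower by camera when a single mouse was left out. These were T cell markers without water 1 (adjusted p = 0.0272) or water 5 (0.0188), NF-kB targets without nicotine 2 (0.0439) and mast cell markers without nicotine 5 (0.0416). The differences were -0.17 for NF-kB target genes, -0.13 for T cell markers, -0.12 for B and plasma cell markers, -0.03 for neutrophil markers and -0.15 for mast cell markers. The members with the smallest p were Rel (-0.56 ± 0.21 SE) and Cxcl1, then Cd3g (-0.54 ± 0.21) and Gzmb (-0.51 ± 0.26), Cd79b (-0.24 ± 0.07) and Ighm (-0.12 ± 0.06), Csf3r (-0.11 ± 0.08) and Camp (0.12 ± 0.09), and the mast cell protease genes Mcpt4 (-0.57 ± 0.14) and Cpa3 (-0.98 ± 0.30). In the mast cell list 2 of 6 members passed over the list alone, and the exact permutation p of its mean was 0.0317, or 0.141 after adjustment.

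The third question was whether immune and inflammation genes differ together, as the series title names such a signature. Over the 164 tested members of the 10 immune lists, the mean was 8.15 ± 0.54 (SD, n = 5) in nicotine mice and 8.49 ± 0.09 (SD, n = 5) in water mice. The difference of -0.34 log2 units did not pass the exact two-sided permutation test (p = 0.254), with 134 members lower and 30 higher and 0 past the threshold over the list alone by limma. Nicotine 3 had a mean of 7.30 and nicotine 1 a mean of 7.93, and the other 3 nicotine mice lay between 8.38 and 8.59. Leaving both out, the difference was 0.02 with an exact permutation p of 0.875.

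The 5 other lists called lower were 3 lists of tissue markers, a drug metabolism list and a stress list. Prostate luminal secretory and androgen-regulated genes differed by -0.84 log2 units, with 26 of 28 members negative and 0 past the threshold over the list alone; Fkbp5 (-0.52 ± 0.25 SE), the transcription factor gene Foxa1 (-0.22 ± 0.11) and Cldn10 (-1.14 ± 0.62) had the smallest p. Smooth muscle markers differed by -0.59, with all 16 members negative, among them Cald1 (-0.38 ± 0.24 SE), Pgm5 (-0.63 ± 0.41) and Mylk (-0.61 ± 0.41). Nicotine and xenobiotic metabolism genes differed by -0.47, with 17 of 22 members negative and the smallest p for the aldehyde oxidase genes Aox3 (-0.38 ± 0.11 SE) and Aox1 (-0.32 ± 0.12) and the glutathione transferase gene Gsta3 (-0.44 ± 0.15). Endoplasmic reticulum stress genes differed by -0.26, with 18 of 23 members negative and the smallest p for the chaperone genes Dnajb9 (-0.63 ± 0.18 SE) and Canx (-0.15 ± 0.07) and for Sel1l (-0.28 ± 0.12). Seminal vesicle secretory genes differed by -2.09, with all 11 members negative, among them Spinkl (-2.18 ± 1.54 SE), Sva (-2.62 ± 1.87) and Svs3b (-2.34 ± 1.68). Adjusted p by limma camera was 0.000845, 0.00484, 0.000356, 0.00901 and 0.0104 for these 5 lists, and adjusted p was 0.660 for each with an estimated correlation. In the 8 other mice the differences were 0.01, 0.08, -0.08, -0.04 and -0.74, and none of the 5 passed.

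In all, 17 of 31 lists passed by limma camera, 6 higher and 11 lower, 0 passed with an estimated correlation, and 0 passed by fry or by the exact permutation test after adjustment. For the 17 called lists the estimated correlation ran from 0.024 (oxidative phosphorylation) to 0.958 (seminal vesicle), above the preset 0.01 in each. The calls at the preset are therefore lenient wherever these estimates hold. At an unadjusted p under 0.05 there was 1 list by camera with an estimated correlation, 6 by fry and 7 by the exact permutation test. Without nicotine 3, 9 of the 17 calls were lost, and leaving out any other mouse lost 0 to 3, with 3 lost without nicotine 1 and 3 without water 2. The proliferation, fatty acid and cholesterol synthesis, fibroblast and macrophage lists passed by camera with the same direction without nicotine mice 1 and 3 and without each mouse in turn. With an estimated correlation in the 8 mice their adjusted p was 0.393, 0.655, 0.393 and 0.655, so none of the 4 passed. Seminal vesicle content differed between the mice of each group, with 6 mice low in it and 4 high in it, 1 of these with nicotine. The differences within the low and the high mice were 0.95 and 0.31 for proliferation genes and -0.61 and -0.20 for fibroblast genes. They were -0.53 and -0.15 for macrophage markers and 0.23 and 0.07 for fatty acid and cholesterol synthesis genes. The low mice include nicotine mice 1 and 3, so the differences within them are not free of these 2 mice. In proliferation genes nicotine 1 and 3 lay 1.02 and 1.94 above the mean of the 5 water mice, and nicotine 2 and 4 lay 0.32 and 0.29 above it.

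The lists below did not pass by limma camera. Nicotinic acetylcholine receptor subunits, the receptors nicotine acts on, differed by 0.25 log2 units (adjusted p = 0.253), by 0.14 without nicotine 3 and by 0.09 without nicotine mice 1 and 3, and the 8 tested subunits ranged from -0.09 to 1.08. Examples were Chrnb2 (1.08 ± 0.53 SE), Chrna4 (0.75 ± 0.54), Chrna7 (0.16 ± 0.15) and Chrnb4 (0.08 ± 0.11). Chrnb2 was above every water mouse in all 5 nicotine mice, and without nicotine mice 1 and 3 its difference was 0.16 ± 0.06 (SE). Adrenergic and dopamine signalling genes differed by 0.10, with Crem (-0.21 ± 0.07 SE) and Slc6a2 (-0.29 ± 0.14) as the members of smallest p. Epithelial-mesenchymal transition and invasion genes differed by -0.15, and of these the matrix protease gene Mmp2 (-0.58 ± 0.15 SE) passed over the list alone, with Vim next at -0.33 ± 0.12. Immediate early genes differed by 0.00 with a camera test of the opposite sign, and Jun had 0.48 ± 0.21 (SE) and Nr4a3 -0.37 ± 0.21. Without nicotine mice 1 and 3 this list differed by 0.13 and passed by camera as higher (adjusted p = 0.00613). Its adjusted p there was 0.749 with an estimated correlation.

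Among the cell type lists that did not pass, basal epithelial markers had a mean difference of 0.02 and a median of -0.06, with Jag2 at 0.89 ± 0.44 (SE) and Itga6 at -0.34 ± 0.22. Endothelial markers differed by -0.02, although Cd34 passed over the list alone and Tek had -0.36 ± 0.12 (SE); without nicotine mice 1 and 3 this list differed by -0.14 and passed by camera (adjusted p = 8.82e-05), with an adjusted p of 0.655 with an estimated correlation. Adipocyte markers differed by 0.04, with nicotine 4 highest at 8.56 log2 units and Thrsp (0.49 ± 0.22 SE) and Pck1 (0.28 ± 0.14) as the members of smallest p. Urothelial markers differed by -0.30, with Upk1b at -1.38 ± 0.89 (SE) and Sprr1a at -0.84 ± 0.71. Nerve and Schwann cell markers differed by 0.32, with the neurofilament genes Nefl at 1.25 ± 0.71 (SE) and Nefh at 0.47 ± 0.30. Of the erythrocyte genes 4 were tested, too few for the list test; Alas2 had -0.23 ± 0.06 (SE), Car2 -0.61 ± 0.46, Slc4a1 0.03 ± 0.07 and Car1 0.01 ± 0.16.

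Pbsn, whose promoter drives the transgene, had 11.2 ± 0.26 log2 units (SD, n = 5) in water mice and 9.67 ± 2.79 (SD, n = 5) in nicotine mice, a difference of -1.50 ± 1.13 (SE) with a limma adjusted p of 0.488. Nicotine 3 had 5.08 and nicotine 1 had 9.17, and without these 2 mice the difference was 0.20 ± 0.27 (SE).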

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

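All tests in this part were chosen after the results they bear on were seen. A sample was singled out where its gap to the nearest mouse of its group, divided by the range of the group, was above 0.71, the critical value for 5 mice. Of 266 groups of 5 values tested, 28 had such a mouse, where chance gives about 1 in 20, or 13.3; 12 of the 28 lay in nicotine 3, 6 in nicotine 1, 4 in other nicotine mice and 6 in water mice.

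Nicotine 3 was far below the other nicotine mice, in log2 units, in luminal genes (7.46, next 10.3), urothelial markers (7.05, next 8.86), endoplasmic reticulum stress genes (9.96, next 10.9) and B and plasma cell markers (7.22, next 7.63). Among single genes it was lowest in Upk1b (6.67), Cldn10 (7.10), Fkbp5 (9.24), Csf1r (8.06), Cd163 (6.34) and Aox3 (6.07), and highest in the nicotinic receptor genes Chrna4 (10.4, next 7.45) and Chrna7 (7.43). Nicotine 1 was far above the others in skeletal muscle markers (9.82, next 7.38) and in their members Myl1 (11.01), Mb (9.29) and Neb (9.08). It was highest in the receptor gene Chrnb4 (7.52) and lowest in the autophagy gene Rb1cc1 (9.03).

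The other nicotine mice singled out were nicotine 5, highest in the seminal vesicle gene Spinkl (11.4, next 7.03), nicotine 4, lowest in Cxcl1 (7.35), and nicotine 2, lowest in Csf3r (6.46) and Ndufb8 (9.49). Among water mice, water 4 was highest in oxidative phosphorylation genes (10.6401, next 10.6048) and Dpy30 (10.6161), water 2 was highest in Cldn10 (11.01) and water 5 lowest in Il33 (8.82). Water 1 was lowest in endoplasmic reticulum stress genes (10.97) and highest in endothelial markers (8.05).

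For the pattern that nicotine 3 and nicotine 1 stand apart with high neuroendocrine markers, a weak array is argued against: 470 genes lay more than 2 log2 units above the highest water mouse on nicotine 3, and 735 lay that far below the lowest. Nerve tissue is a harder case: the full nerve and Schwann cell list, which holds neurofilament genes that neuroendocrine cells can share, was 8.89 on nicotine 3 and 8.46 on nicotine 1 against at most 8.10 in water mice, with Nefl at 11.6 and 9.48 against 7.72. The 6 tested glial and myelin markers left without these filament genes argue against it, with medians -0.19 and 0.12 from the water mean where the median neuroendocrine marker was 3.02 and 1.86; Mbp was 8.48 and 8.91 against 8.79 in water mice, and Pmp22 on nicotine 3 was the exception, at 11.6 against 10.4. A candidate explanation is neuroendocrine tumour in these 2 pieces, with skeletal muscle beside it in nicotine 1, where 15 of 16 muscle markers lay more than 1 log2 unit above the highest water mouse. Whether nicotine has a part in it cannot be told apart from chance with 2 of 5 against 0 of 5 mice (two-sided Fisher exact p = 0.444), and tumour stage and age at collection were not analysed here.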

How the results depend on the processing

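Leaving out nicotine mice 1 and 3 together and the seminal vesicle covariate were added after the data were seen; the other settings were fixed before. The count of genes past the threshold by limma was 0 under 19 of the 20 planned settings and both added ones, and 1096 with array weights. The counts of 6 lists higher and 11 lower by camera became 4 and 3 with array weights, 6 and 3 with the first principal component as a covariate and 5 and 3 without nicotine mice 1 and 3. They were 0 and 0 with an estimated correlation, by fry and by the exact permutation test. Leaving out each mouse in turn gave 4 to 6 lists higher and 4 to 12 lower, the fewest lower without nicotine 3. The pooled immune genes differed by 0.024 with the principal component and 0.018 without nicotine mice 1 and 3, and by -0.45 to -0.13 without each mouse. With no filter the acute phase (-0.245, adjusted p = 0.261) and cytokine (-0.205, 0.106) lists lost their calls, over all probe sets the cytokine list (0.0922), and without the lowest 50% of genes the skeletal muscle list (0.152). With the seminal vesicle covariate the cytokine (0.127), interferon-stimulated (0.266) and smooth muscle (0.0976) lists lost theirs. Calls were gained as lower by T cell (adjusted p = 0.0143) and B cell (0.0374) markers with no filter, and by endothelial markers with array weights (0.0167), the principal component (0.00357), the covariate (0.0211) and without nicotine mice 1 and 3 (8.82e-05). Adipocyte markers gained one as higher with the principal component (0.00169) and without nicotine mice 1 and 3 (0.00613). Immediate early genes turned and passed by camera as higher without nicotine mice 1 and 3 (adjusted p = 0.00613, and 0.749 with an estimated correlation). Leaving out a single mouse also gained calls for T cell, NF-kB target, mast cell and endothelial lists as lower and for adipocyte markers as higher. Oxidative phosphorylation lost its call without water 2 and without nicotine 3, 4 or 5. The cause was not tested. The array values carry no measure of signal over background, so limits for dim genes were not set.

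Some directions turned. Without nicotine mice 1 and 3 the differences were 0.053 for cytokines, 0.278 for interferon-stimulated genes, 0.068 for NF-kB targets, 0.070 for neutrophil, 0.014 for luminal, -0.00028 for adrenergic, -0.0063 for glycolysis, 0.133 for immediate early, 0.080 for smooth muscle and 0.065 for urothelial lists, and 0.012 for Itga6, 0.019 for Pgm5, -0.0013 for Neb, 0.283 for Sprr1a and 0.199 for Pbsn. With array weights they were 0.042 for cytokines, 0.334 for interferon-stimulated genes, 0.069 for NF-kB targets, 0.051 for neutrophil, -0.00015 for glycolysis, 0.186 for immediate early, 0.109 for smooth muscle and 0.036 for urothelial lists, and 0.0035 for Itga6, 0.032 for Cald1, 0.052 for Pgm5, 0.029 for Mylk and 0.237 for Sprr1a. With the principal component they were 0.044 for cytokines, 0.257 for interferon-stimulated genes, 0.076 for NF-kB targets, 0.0025 for B cell, 0.079 for neutrophil, 0.182 for luminal, 0.023 for endoplasmic reticulum stress, 0.138 for immediate early, 0.170 for smooth muscle and 0.203 for urothelial lists, and -0.062 for Chrna4, 0.030 for Pgm5, 0.047 for Mylk, 0.068 for Upk1b, 0.302 for Sprr1a, 0.345 for Pbsn and -0.035 for Chrna7.

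Other turned values lay near 0. Immediate early genes had 0.0022 with no filter, 0.020 without the lowest 50% of genes, 0.0081 over all probe sets, 0.029 after quantile normalization, 0.033 after median centring and 0.049 with the seminal vesicle covariate. Neutrophil markers had 0.0066 with no filter, 0.0040 after centring and 0.0062 with the covariate. Endothelial markers had 0.019 after quantile normalization and after centring, adipocyte markers -0.068 without the lowest 50%, and Hk1 0.048 as the mean of its probe sets. Leaving out each mouse in turn gave -0.060 to 0.038 for neutrophil, -0.052 to 0.092 for basal epithelial, -0.058 to 0.080 for immediate early, -0.014 (without nicotine 1) to 0.651 for skeletal muscle, -0.081 to 0.039 for endothelial, -0.145 (without nicotine 4) to 0.194 for adipocyte and -0.397 to 0.061 (without nicotine 3) for urothelial lists.

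Of 675 list values under the alternatives, 551 kept direction and side of the threshold, 57 lost and 14 gained a call, and 53 turned. Of 2186 values of named genes 2120 kept both, 48 passed, all with array weights, and 18 turned. With the mouse number as a replicate block, limma called 0 genes, and 5 lists were higher and 10 lower by camera; the cytokine (adjusted p = 0.0626) and oxidative phosphorylation (0.0626) lists lost their calls. Deviations of same-numbered mice from their group means correlated at 0.023, -0.13, -0.082, 0.0094 and 0.16. Of 10 mice, 1 correlated best with its own number. Nicotine mice 1 and 3 move the mean of their group, and so the deviations of its other mice. These correlations therefore cannot decide whether the numbers pair the mice.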

Other observations

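The genes in this paragraph were chosen after their values were seen. Nicotine 3 had low levels of markers of the prostate epithelium: Msmb was 6.21 log2 units against 13.3 ± 0.02 (SD, n = 5) in water mice, Krt18 6.94 against 12.6 ± 0.04, Krt8 7.98 against 12.5 ± 0.09 and the adhesion gene Cdh1 6.79 against 11.9 ± 0.10. The prostate transcription factor gene Hoxb13 was 10.2, against 11.02 ± 0.19 (SD, n = 5), and Epcam was 9.61. Genes far above the water mean in nicotine 3 included Syt1 (by 5.17 log2 units), Elavl4 (5.06), the granin gene Scg3 (5.03), the splicing factor gene Nova1 (4.87) and the transcription factor gene Sox11 (4.77). Nicotine 1 shared Syt1 (4.36), Prox1 (4.63, and 4.49 in nicotine 3) and Necab1 (4.80, and 4.42), but kept Msmb at 12.99, Krt18 at 12.4 and Cdh1 at 11.6, while its Hoxb13 was 9.98 and its Pbsn 9.17 against 11.2 in water mice. Genes high in nicotine 1 included Caln1 (5.28), Pcsk1 (4.71), a prohormone convertase, and Ddc (4.83), which makes dopamine and serotonin. Foxa2, a transcription factor of neuroendocrine prostate tumours in mice, was 9.69 in nicotine 1 and 7.54 in nicotine 3, against 7.50 ± 0.09 (SD, n = 5) in water mice. The proliferation marker Mki67 was 12.3 in nicotine 3, 11.5 in nicotine 1 and between 10.6 and 10.8 in the other 3 nicotine mice, against 10.2 ± 0.21 (SD, n = 5).

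All tests below were chosen after the results they bear on were seen. Histone genes, many of which are expressed during DNA replication, were examined as a family because H2bc18 had a small unadjusted limma p (0.00179, adjusted 0.458). Of 26 tested genes with H1f, H2ac, H2bc, H3c or H4c symbols, 24 had a positive difference and 12 were above every water mouse in all 5 nicotine mice. The family mean was 9.63 ± 0.42 (SD, n = 5) in nicotine mice and 9.03 ± 0.09 (SD, n = 5) in water mice, with an exact two-sided permutation p of 0.00794, the smallest possible. H1f5 differed by 0.99 ± 0.26 (SE), H4c3 by 0.97 ± 0.28 and H2bc14 by 0.95 ± 0.23. Without nicotine mice 1 and 3 the family differed by 0.30 (exact permutation p = 0.0179), and after quantile normalization or median centring by 0.63. Like the proliferation list, the family mean was above all water mice in all 5 nicotine mice. The test compared the 2 groups only. Whether histone genes move with the proliferation list from mouse to mouse was not tested. H2bc18 is itself a member of the family, so the test depends on the choice. Small nucleolar RNAs, examined because Snord118 and Snora41 had similar p, differed by 0.19 over 45 genes, with 35 positive, 3 above every water mouse in all nicotine mice and an exact permutation p of 0.0635, so they were not shown to be higher as a family.

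Proliferation genes were higher in every nicotine mouse. Nicotine mice 1 and 3 as the whole source are argued against by the other 3 mice, all above the highest water mouse, with a difference of 0.32 where the water SD was 0.0996. A larger share of luminal epithelium is argued against in the same 8 mice, where the luminal list differed by 0.014 ± 0.039 (SE between mice) and the proliferation list minus the luminal list, taken per mouse, by 0.31 ± 0.04. Seminal vesicle tissue as the whole source would need lower proliferation genes in the water mice that hold it, and the 3 water mice high in it differed from the 2 low in it by 0.094 ± 0.090 (SE), in the other direction; with the list as a covariate the nicotine difference was 0.64 ± 0.35, under 2 SE from 0, and its exact permutation p within classes of content was 0.0833. An effect of nicotine and a larger share of tumour in these pieces stay open, and the share of tumour was not tested.

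Fibroblast and macrophage lists were lower in nicotine mice. Nicotine mice 1 and 3 alone are argued against for the fibroblast list (-0.40 without them, all 3 others below the lowest water mouse), while for the macrophage list (-0.25) nicotine 2 and nicotine 5 overlapped the water mice and this cannot be told apart. A share of stroma that falls alike for all its cell types is argued against by smooth muscle markers. In those 8 mice these differed by 0.08 ± 0.10 (SE between mice), and by 0.48 ± 0.10 when the fibroblast list was subtracted per mouse. For a share of stroma without muscle, endothelial markers fell less (-0.14 ± 0.05, and 0.25 ± 0.05 after the subtraction). They cannot decide it, because a dimmer list can show a smaller log2 change for the same loss. The endothelial list averaged 7.94 log2 units in water mice, against 9.36 for the fibroblast list, and limits for dim genes were not set. Seminal vesicle tissue as the whole source would need higher lists in the water mice that hold it. The 3 high water mice differed from the 2 low ones by -0.17 ± 0.11 (SE) in the fibroblast list, which argues against it. In the macrophage list they differed by -0.19 ± 0.18, too wide a spread to decide. With seminal vesicle content as a covariate the nicotine differences were -0.45 ± 0.17 and -0.38 ± 0.16. The exact permutation p within classes of content was 0.0333 for the fibroblast list and 0.0667 for the macrophage list. Both of these tests include nicotine mice 1 and 3, which were low in content, so for macrophage markers they do not decide it. Fewer fibroblasts, or fibroblasts with less matrix expression, may also underlie the pattern, and nicotine as its source stays a hypothesis.

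The counts were set against 100 of the 126 splits of the 10 mice into 5 and 5, the real split included. The count of 0 genes past the threshold by limma was reached by all 100 splits, with a highest other of 0. The 1514 genes at an unadjusted p under 0.05 were reached by 1 split, the real one, with a highest other of 1343 and a median of 235. The other 26 splits were not run. The count was 625 with the seminal vesicle list mean as a covariate and 784 without water 3, where 5% of the tested genes is 747.65. These were the lowest counts of all settings, and every other setting gave 981 or more. The count thus depended on the setting, and these splits alone do not exclude chance for it. The 733 genes with groups that did not overlap were likewise reached by 1 split, with a highest other of 550 and a median of 83. In the split with 550, nicotine 4 and water 2 changed places. The 17 lists past the threshold by camera were reached by 20 of 100 splits, with a highest other of 20 and a median of 13, so chance was not excluded for the number of lists. Of the 44 other splits that put nicotine mice 1 and 3 on the same side, 16 gave at least 17 lists and 0 gave at least 733 genes without overlap.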
